A study of Mus musculus with 8 samples.

How the data were processed

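Transcript levels were measured in primary fibroblasts isolated from mouse hearts, wild type or labelled as Siah knockout. Per the labels' protocols, the cells were grown in DMEM with 10% FBS and either left untreated or placed at 1% O2 for 6 h, RNA was extracted with RNeasy columns, and it was amplified and labelled with the Agilent Low-Input QuickAmp kit. The single dye was Cy3, so each sample has 1 value per spot. The series' design text describes the 2 samples of each of the 4 groups as biological replicates. It does not say which samples share an animal or a culture, and p-values measure the spread between these samples.

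The authors deposited a table of 8 columns by 62976 spots, whose values were taken as log2 intensities. That log base was read from the values, which ran from 2.13 to 16.0, and is not given in the sources used here. The 8 columns shared nearly the same quantiles, with a median of 3.94 in each, so the deposited values had already been brought to a common distribution. The background correction and the normalization method are also not given in the sources used here. Per the submitters' processing notes, limma was used, with no version given. In all, 10 of the deposited values were missing, and no column was left out.

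Spots were named through the platform annotation, with symbols brought up to date through a RefSeq gene table of the assembly GRCm38.p6, which was used for names and for which genes neighbour each other. Of the 62976 spots, 43941 had 1 gene and 19035 had none; 0 had several. The symbol came from a matched accession for 33708 spots and from a synonym for 463, and 9770 kept the symbol of the annotation. For the 11040 genes with more than 1 spot, the spot with the highest mean over the 8 samples stood for the gene. The dimmest 30% of the 24306 genes by that mean were removed, which left 17014 genes above a mean of 3.39.

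The deposited values were fitted without further normalization in limma 3.58.1 under R 4.3.3, with lmFit and eBayes, a mean for each of the 4 groups, no variance trend and no robust fit. All 8 samples entered, so that the groups shared an estimate of the spread with 4 residual degrees of freedom, to which eBayes added 2.25 prior degrees of freedom. The comparisons were hypoxia against normoxia in wild-type and in knockout-labelled cells, knockout-labelled against wild type in normoxia and in hypoxia, the difference of the hypoxia responses, and the averages of the hypoxia and of the genotype comparisons. Within each comparison p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. If no gene changed, 851 of the 17014 would be expected at an unadjusted p under 0.05 in each comparison. Every log2 fold change is hypoxia minus normoxia or knockout-labelled minus wild type, and SE is limma's moderated standard error.

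The gene lists were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over the lists and comparisons of each kind, and again with the correlation estimated for each list and with fry. The lists covered HIF targets, glycolysis, collagen-modifying enzymes, matrix and myofibroblast genes, NF-kB targets, interferon-stimulated genes, the cell cycle, the respiratory chain, the unfolded protein and ATF4 response, sterol synthesis, p53, NRF2, YAP and TEAD, and Wnt targets, immediate early genes, and the Siah family with the oxygen-sensing machinery. Marker lists covered fibroblasts, cardiomyocytes, endothelium, macrophages and leukocytes, smooth muscle and pericytes, epicardium and mesothelium, Schwann and neural cells, adipocytes, skeletal muscle and sex-linked transcripts. Some lists share genes, such as Pdk1, Slc2a1, Pfkfb3 and Pfkfb4 on the HIF and glycolysis lists.

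The design, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. By that rule the text names up to 10 called genes at each end of a comparison, the Siah genes in every sample, other called oxygen-sensing genes, and up to 4 called members of each list, or up to 2 with the smallest p where none was called. Genes named beyond it are said to have been chosen after their values were seen. The alternatives were quantile normalization, shifts to a common median or 75th percentile, other filters and spot rules, a variance trend, a robust fit, sample weights, fits of only the groups compared, the replicate number as a block, and the removal of each sample in turn. Added after the data were seen were an additive model, crossed numbers as a block, the culture as a fixed or random block, and the removal of X and Y genes.

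The fit was tested on simulated data with 17011 genes. For hypoxia in wild-type cells it called 8.36% of genes changed by a log2 of 1, 48.7% of those changed by 2 and 86.7% of those changed by 4. For the average over genotypes it called 35.8%, 72.5% and 97.0%, and for the average over oxygen 33.1%, 72.5% and 96.4%. The list test, simulated for hypoxia in wild-type cells on the same genes, called the HIF list shifted by 1 in 20 of 20 runs. It called the unshifted list in 0 of 20. The simulated noise was drawn independently for each gene and sample. These rates therefore do not cover correlated genes or shared cultures. The number of arrays limits the precision: the median SE of a log2 fold change between 2 groups was 0.30. Spots without a gene name stayed out of the comparisons and were tested apart.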

Results

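Siah proteins are ubiquitin ligases, and Siah2 is known to act on the prolyl hydroxylases that mark the hypoxia-inducible factor HIF for degradation. Fibroblasts from wild-type hearts and from hearts labelled as Siah knockout were compared in normoxia and after 6 h at 1% O2, with 2 samples in each of the 4 groups. The array gave values for 62976 spots, and 17014 genes were tested. Across spots, which are not independent replicates, samples of the same group correlated with r of 0.984 to 0.987, and samples of different groups with r of 0.984 to 0.990. The first principal component, with 31.7% of the variance, set replicate 2 of the wild-type groups (-40.0 in normoxia, -43.1 in hypoxia) against replicate 2 of the knockout-labelled groups (42.5 and 38.7). Replicate 1 ran the other way, at 18.8 and 8.89 for wild type and -7.66 and -18.1 for knockout-labelled cells, so this component did not separate the genotypes. The replicate 2 samples also lay furthest apart in the macrophage and leukocyte markers described with the genotype comparison. The second component, with 19.7% of the variance, did separate the genotypes. On it every wild-type sample lay at 7.17 or higher and every knockout-labelled sample at -10.9 or lower.

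The label names Siah without saying which member of the family was altered, so all 4 Siah genes were read in every sample first. Siah2 gave log2 values of 9.04 and 8.71 in wild-type normoxia and 9.55 and 8.96 in wild-type hypoxia. In knockout-labelled cells it gave 6.60 and 7.39 in normoxia but 9.29 and 8.87 in hypoxia, the range of the wild type. Siah1a lay between 8.78 and 9.44 in all 8 samples, and Siah1b between 7.89 and 8.81. Siah3 was dim, between 3.64 and 6.60. Adjusted over the oxygen-sensing list alone, Siah2 was lower in knockout-labelled normoxia (log2 fold change -1.88, SE 0.35, adjusted p = 0.0445) and rose with hypoxia in knockout-labelled cells (2.08, SE 0.35, adjusted p = 0.0182). Over all genes in limma the adjusted p was 0.415 and 1.00. Its log2 fold change was 0.38 (SE 0.35) with hypoxia in wild-type cells and -0.18 (SE 0.35) between the genotypes in hypoxia. The difference of the hypoxia responses was 1.70 (SE 0.50), with an adjusted p of 0.378 over the list alone. Siah1a differed by 0.31 in normoxia and 0.25 in hypoxia between the genotypes, Siah1b by 0.69 and 0.14, and Siah3 by 1.10 and -0.27; none of these was called. Each gene was read by 1 spot whose place relative to the altered part of the gene is not known, so these values do not check the genotype labels. The Siah2 call in normoxia was lost without any sample other than knockout-labelled normoxia replicate 2: the adjusted p over the list alone was then 0.337 without wild-type normoxia replicate 1, 0.248 without knockout-labelled normoxia replicate 1, 0.0841 without either knockout-labelled hypoxia sample, 0.0819 without wild-type normoxia replicate 2, and 0.0615 without either wild-type hypoxia sample. The call with hypoxia was lost without knockout-labelled hypoxia replicate 1 (0.103) or 2 (0.0856) or normoxia replicate 1 (0.0709).

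**Figure D1:**
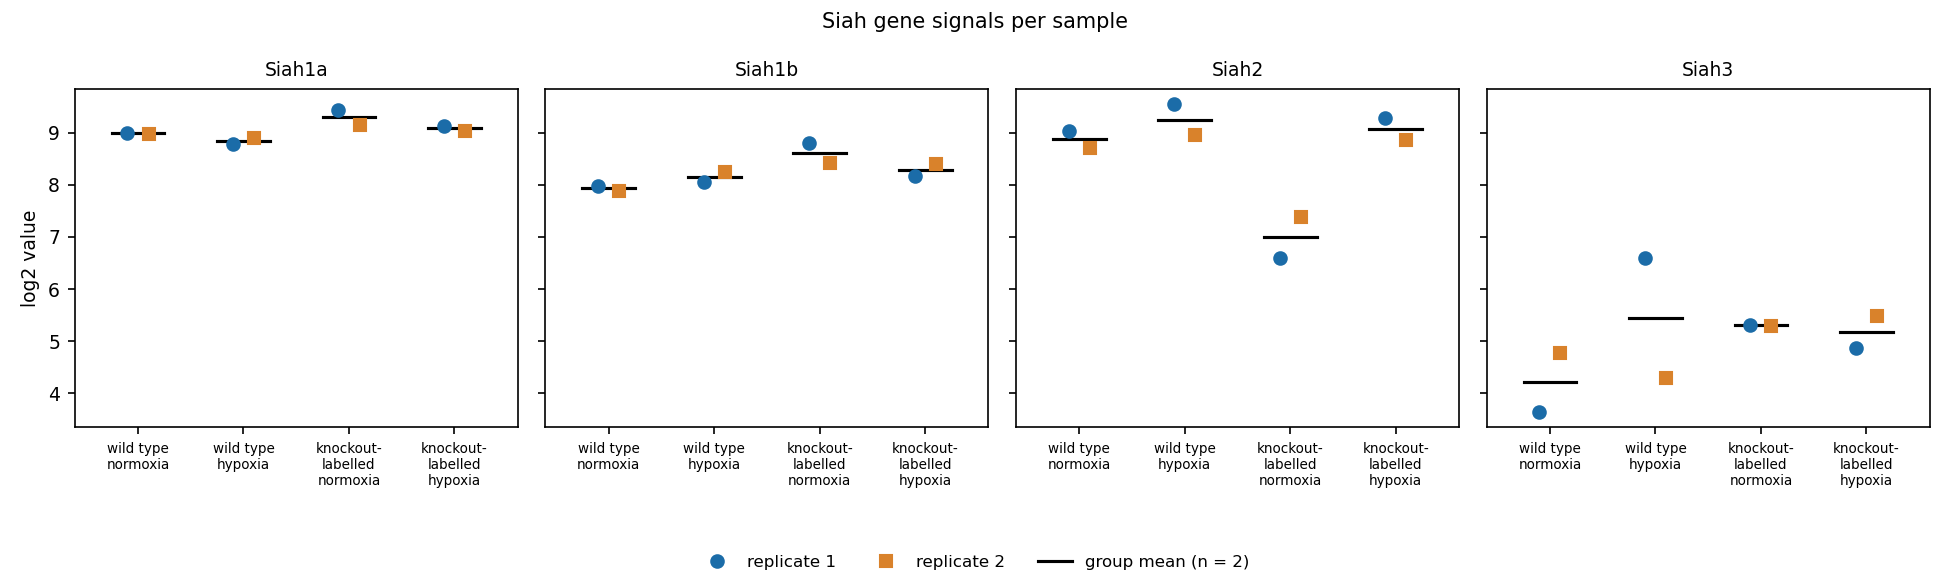
Log2 values of Siah1a, Siah1b, Siah2 and Siah3 in each of the 8 samples, with circles for replicate 1, squares for replicate 2 and bars for the mean of the 2 samples of a group. Siah2 lies at 6.60 and 7.39 in knockout-labelled normoxia and between 8.71 and 9.55 in the other groups.

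The HIF target list rose with low oxygen in wild-type cells. Of 35 measured members, 34 were higher, with a median log2 fold change of 1.23, and the list passed camera at an adjusted p of 1.87e-34, but not at an adjusted p = 0.316 with an estimated correlation. Ankrd37, an ankyrin-repeat protein, had a log2 fold change of 4.26 (SE 0.69), and Egln3, an oxygen-sensing prolyl hydroxylase, 3.51 (SE 0.58). Bnip3, a mitophagy receptor, had 2.64 (SE 0.39), and the oxidoreductase Ero1a 1.52 (SE 0.20). The list of glycolysis and glucose uptake also rose as a whole, with 25 of 26 members higher and a median of 0.67 (adjusted p = 1.75e-19, and adjusted p = 0.316 with an estimated correlation). Adjusted over the list alone, 19 HIF targets and 9 glycolysis genes were called. Over all genes limma called 0, with 616 at an unadjusted p under 0.05, fewer than the 851 expected by chance. That shortfall depended on the fit. With the culture, taken as genotype and replicate number, as a fixed or random block, 1174 and 1217 genes had such a p. With crossed replicate numbers as a block 1159 did, and 0 genes were called in each of these fits. Without wild-type hypoxia replicate 2 fewer HIF targets and no glycolysis genes were called over the list alone. Calls over all genes without wild-type hypoxia replicate 1 or 2 rested on the 1 sample left in that group. They were Plxna4os1 (log2 fold change 10.5) and Zfp872 (5.54) in turn, named after their values were seen and not called with all samples.

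Knockout-labelled cells answered low oxygen in the same direction. The HIF targets were higher for 34 of 35 members, with a median log2 fold change of 0.89 (adjusted p = 6.58e-31), and the glycolysis genes for 23 of 26, with a median of 0.43 (adjusted p = 5.32e-16). With an estimated correlation both lists had an adjusted p = 0.316. Ankrd37 had a log2 fold change of 4.02, Egln3 3.23, Bnip3 2.45 and Ero1a 1.11. Adjusted over the list alone, 14 HIF targets and 6 glycolysis genes were called. Over all genes limma called 0, with 443 at an unadjusted p under 0.05, fewer than the 851 expected by chance. With the culture as a fixed or random block 870 and 925 genes had such a p, and with crossed replicate numbers 822. Again 0 were called in each. Without knockout-labelled hypoxia replicate 1 the calls over the list alone were 0 and 3, and without knockout-labelled normoxia replicate 1 they were 4 and 2. With the mean over a gene's spots 8 HIF targets were called. Calls over all genes without knockout-labelled hypoxia replicate 2 rested on the 1 sample left in that group. Among them were Gm32947 (log2 fold change 8.77) and Cyp2d37-ps (6.45), named after their values were seen and not called with all samples.

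**Figure D2:**
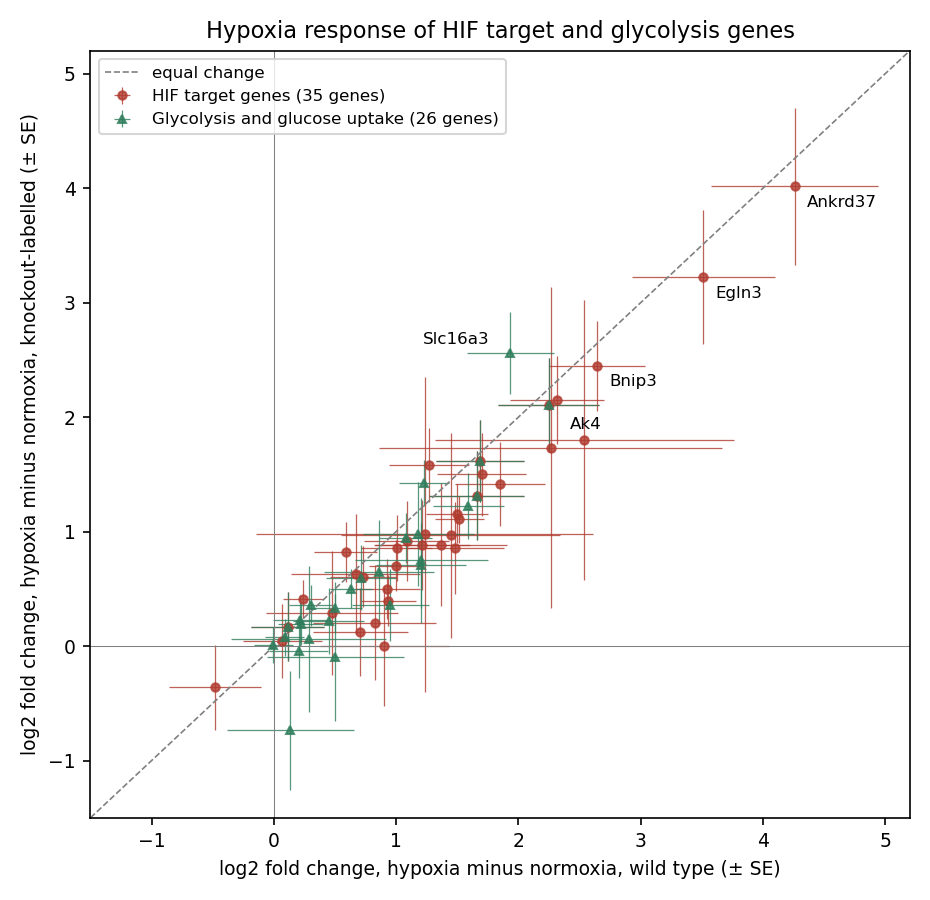
Log2 fold change with hypoxia in wild-type cells (horizontal, ± SE) against knockout-labelled cells (vertical, ± SE), with red circles for the 35 HIF target genes, green triangles for the 26 glycolysis genes, and a dashed line of equal change; genes on both lists are drawn in both colours. Ankrd37 lies furthest out, at 4.26 and 4.02.

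Averaged over the genotypes, 4 samples against 4, the HIF targets had a median log2 fold change of 1.10 (34 of 35 higher, adjusted p = 2.42e-44) and the glycolysis genes 0.61 (25 of 26 higher, adjusted p = 1.8e-24); with an estimated correlation each had an adjusted p = 0.316. Adjusted over the list alone, 23 HIF targets and 11 glycolysis genes were called. The largest HIF members were Ankrd37 (4.14, SE 0.48), Egln3 (3.37, SE 0.41), Bnip3 (2.55, SE 0.28) and Ak4, a mitochondrial adenylate kinase (2.23, SE 0.27). Pdk1, a kinase that inhibits pyruvate dehydrogenase, rose by 2.18 (SE 0.29), the glucose transporter Slc2a1 by 1.49 (SE 0.27) and the angiogenic factor Vegfa by 1.60 (SE 0.26). Car9 was the member with a negative value, at -0.42 (SE 0.27). Of the glycolysis genes, the lactate transporter Slc16a3 rose by 2.25 (SE 0.25), glycogen synthase Gys1 by 1.41 (SE 0.20) and Pfkl by 1.33 (SE 0.14). Several of these members were chosen after their values were seen. Over all genes limma called 0 (smallest adjusted p 0.147), with 639 at an unadjusted p under 0.05, fewer than the 851 expected by chance. With the culture as a fixed or random block 1238 and 1204 genes had such a p, and with crossed replicate numbers 1211. The number of genes called was 15 with a variance trend, 15 with the culture as a random block and 8 with an additive model. It also changed without wild-type hypoxia replicate 1 or knockout-labelled hypoxia replicate 2, where 1 sample was left in the group. Plxna4os1 (5.16) and Gm32947 (4.25) were called there in turn, named after their values were seen and not called with all samples.

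The p53 target genes were lower with hypoxia by a small amount: 22 of 24 members in the average, with a median log2 fold change of -0.19 (adjusted p = 3.11e-05, and adjusted p = 0.796 with an estimated correlation). The medians were -0.18 in wild-type cells (adjusted p = 0.00267) and -0.20 in knockout-labelled cells (adjusted p = 0.00187), each with an adjusted p = 0.824 with an estimated correlation. No member was called; the smallest p belonged to the receptor Eda2r (-0.45, SE 0.15) and the cytokine Gdf15 (-0.81, SE 0.34). The wild-type call was lost with the mean over a gene's spots (0.0581) and without wild-type hypoxia replicate 1 (0.263) or normoxia replicate 2 (0.128). The knockout-labelled call was lost without knockout-labelled normoxia replicate 1 (0.400) or hypoxia replicate 2 (0.0958). The other lists did not pass in the average. The NF-kB inflammatory genes had a median of -0.11 (adjusted p = 0.0636) and the collagen-modifying enzymes 0.06 (adjusted p = 0.0731). The oxygen-sensing list had a median of -0.05 but a mean of 0.20, and the unfolded protein list a median of -0.02 but a mean of 0.10; adipocyte markers and matrix genes also had a negative median beside a positive mean. Members called over their list alone and chosen after their values were seen were Krt19 (1.69, SE 0.20), the collagen prolyl hydroxylase P4ha2 (0.85, SE 0.16), Ier3 (1.59, SE 0.28), Vhl (0.75, SE 0.16), Trib3 (0.82, SE 0.18) and Vldlr (1.64, SE 0.23).

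Whether the response to low oxygen differed between the genotypes was tested as a difference of the 2 responses. The HIF targets had a median difference of -0.26, lower in knockout-labelled cells for 30 of 35 members, and did not pass (adjusted p = 0.0646, and adjusted p = 0.966 with an estimated correlation). They passed with the culture as a fixed block (0.0387), with the dimmest 50% of genes removed (0.0155), and without knockout-labelled hypoxia replicate 1 (0.00210), wild-type hypoxia replicate 1 (6.1e-06) or knockout-labelled normoxia replicate 1 (0.00677), and turned in direction without wild-type hypoxia replicate 2 (0.761). The interferon-stimulated genes passed in the other direction, with a median of 0.39 and 28 of 28 members higher (adjusted p = 0.0201, and adjusted p = 0.966 with an estimated correlation). Their median was -0.25 with hypoxia in wild-type cells (adjusted p = 0.0893) and 0.13 in knockout-labelled cells (adjusted p = 0.277), and Oasl1 had a difference of 0.79 (SE 0.75). That call was lost without wild-type hypoxia replicate 1 (0.0663) or 2 (0.0626) or knockout-labelled normoxia replicate 2 (0.0944), and the direction turned without knockout-labelled hypoxia replicate 1 (0.333) or wild-type normoxia replicate 2 (0.714). Over single genes limma called 0, with 416 at an unadjusted p under 0.05, fewer than the 851 expected by chance. With the culture as a fixed or random block 751 and 854 genes had such a p, and with crossed replicate numbers 664. Again 0 were called in each. The number called changed without knockout-labelled hypoxia replicate 2 or wild-type hypoxia replicate 1. The added calls rested on the 1 sample left in that group. Gm32947 (9.04) and Plxna4os1 (-10.8) were among them in turn, named after their values were seen and not called with all samples.

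Between the genotypes the named gene that differed most was Eif2s3y, a translation initiation factor encoded on the Y chromosome. It averaged 8.93 (SD 0.14, n = 4) in wild-type samples and 3.61 (SD 0.28, n = 4) in knockout-labelled samples, a log2 fold change of -5.33 (SE 0.16, adjusted p = 0.000553). Xist, the X-inactivation transcript, was higher in knockout-labelled samples (1.58, SE 0.22; 5.19 against 3.61) when adjusted over the sex-linked list alone (adjusted p = 0.000548). Kdm5d and Uty, also on the Y chromosome, averaged 6.05 and 4.29 in wild-type samples and 5.96 and 3.88 in knockout-labelled samples at their brightest spots. Their other spots differed: a dimmer Kdm5d spot with a mean of 4.72 gave -3.03 between the genotypes and a dimmer Uty spot with a mean of 3.51 gave -1.41, the remaining Kdm5d spots, with means of 3.24 or less, gave -0.51 to -0.12, the dimmest Uty spot gave 0.11, and the second Eif2s3y spot gave -4.17. In knockout-labelled samples the Kdm5d, Uty and Eif2s3y spots that gave -3.03, -1.41 and -4.17 averaged 3.20, 2.81 and 2.61, under the level of 3.39 below which genes were left out as dim, so these differences are lower bounds in size. In the average over oxygen 1693 genes had an unadjusted p under 0.05, against 851 expected by chance. There limma called 8 genes, 1 higher and 7 lower. The receptor phosphatase Ptprz1 was higher (1.96, SE 0.15). Haptoglobin, Hp, was lower (-2.46, SE 0.17), as were the folate receptor Folr2 (-2.22, SE 0.14), the vesicle GTPase Rab3b (-1.78, SE 0.15), the coagulation factor chain F13a1 (-1.67, SE 0.14), myosin light chain kinase Mylk (-1.66, SE 0.13) and the fatty acid transporter Cd36 (-1.61, SE 0.13). Their adjusted p was 0.0216 for Folr2 and 0.0298 for the others. The other spots of Ptprz1 (means 3.01 and 2.88) gave 0.09 and -0.08, and those of F13a1 (3.27 and 2.98) gave -0.16 and -0.24. These spots lay under the level of 3.39, where a change may not show. The other spots of Mylk, with means of 6.35, 4.16, 4.16 and 3.24, gave -1.91, -0.85, 0.01 and -0.13. With the mean over spots, which takes in the dim ones, these 3 genes were not called (0.66, -0.69 and -0.91). In normoxia and in hypoxia alone limma called 1 gene each, Eif2s3y (-5.18 and -5.47). Unadjusted p was under 0.05 for 1102 and 1062 genes, against 851 expected by chance.

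The number of genes called in the average over oxygen rested on single samples. It was 1, Eif2s3y, without knockout-labelled hypoxia replicate 1, either wild-type normoxia sample, either knockout-labelled normoxia sample or wild-type hypoxia replicate 2, 3 without wild-type hypoxia replicate 1, of which Eif2s3y was among the 8, and 12, of which 3 were, without knockout-labelled hypoxia replicate 2. It was 62 with a variance trend, 103 with an additive model and 45 with the dimmest 50% of genes removed. It was 453 with crossed replicate numbers as a block, which join knockout-labelled replicate 1 with wild-type replicate 2. With the culture, taken as genotype and replicate number, as a random block it was 1, Eif2s3y, and the other 7 genes were not called. In normoxia it was 0 without either wild-type sample or knockout-labelled replicate 2. In hypoxia it was 0 without knockout-labelled hypoxia replicate 1, 8 without knockout-labelled hypoxia replicate 2 and 3 without wild-type hypoxia replicate 2. Without wild-type hypoxia replicate 1 Eif2s3y was not called in hypoxia (adjusted p = 0.0535), and the 1 gene called was Plxna4os1, named after its value was seen.

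**Figure D3:**
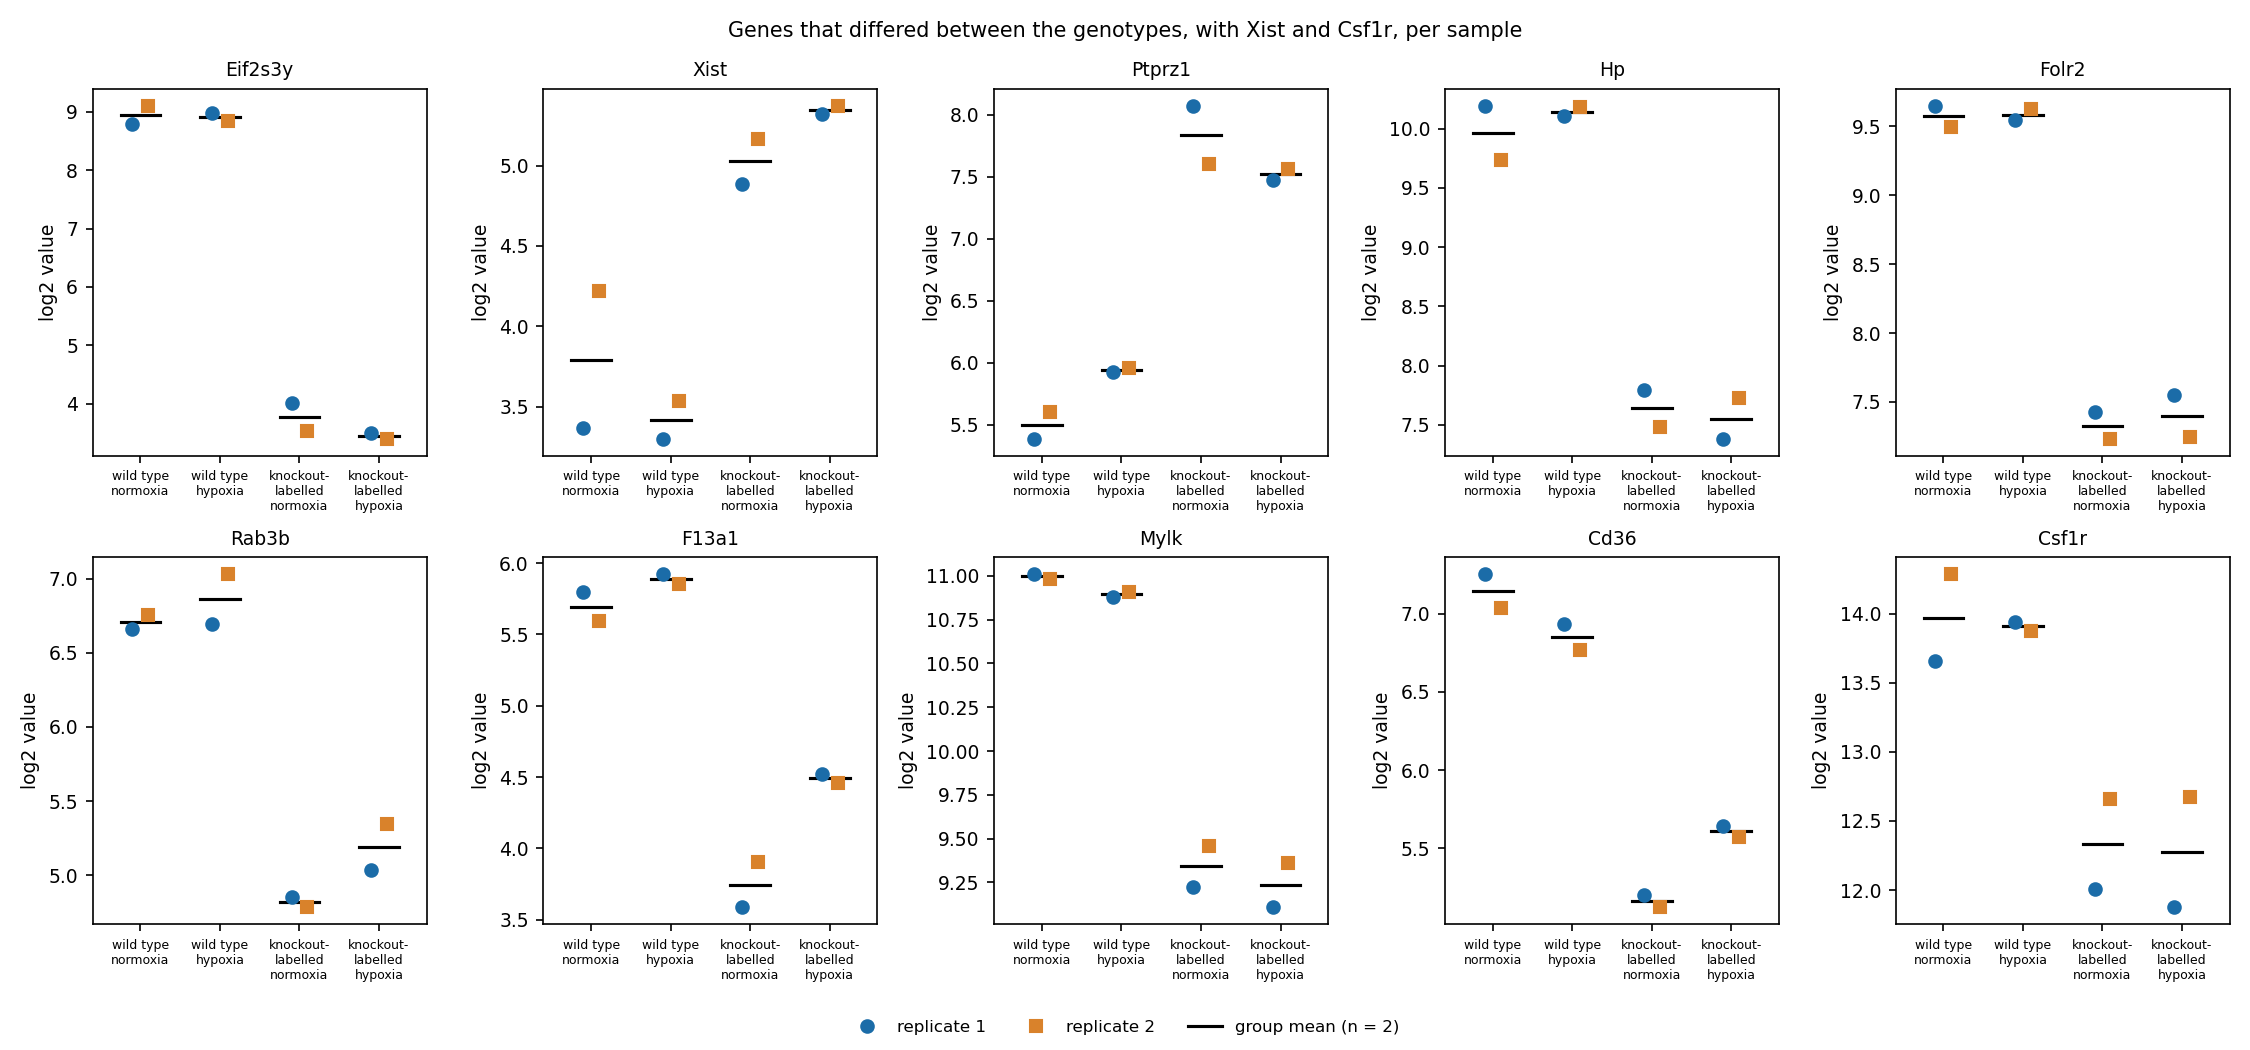
Log2 values per sample of the 8 genes called between the genotypes in the average over oxygen, with Xist and Csf1r, drawn with circles for replicate 1, squares for replicate 2 and bars for the mean of the 2 samples of a group; each panel has its own vertical range. Eif2s3y averages 8.93 in wild-type and 3.61 in knockout-labelled samples.

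Macrophage and leukocyte markers were lower in knockout-labelled samples, 17 of 17 in the average over oxygen with a median log2 fold change of -1.24 (adjusted p = 3.7e-11). The median was -1.25 in normoxia (adjusted p = 1.39e-09) and -1.16 in hypoxia (adjusted p = 5.66e-09); with an estimated correlation each of the 3 had an adjusted p = 0.960. Adjusted over the list alone 14 members were called, and 0 over all genes with limma, where the average had 1693 genes at an unadjusted p under 0.05. The growth factor receptor Csf1r was lower by a log2 fold change of -1.64 (SE 0.27), the mannose receptor Mrc1 by -1.70 (SE 0.61), Cd52 by -1.34 (SE 0.38) and Cd14 by -1.29 (SE 0.42). Itgam, Lyz2 and Lyz1 were not called at their brightest spots. That of Lyz2 lay near the top of the scale, with a mean of 15.8, and its second spot, with a mean of 12.2, gave -1.49. Itgam gave -0.32 at its brightest spot and -2.03, a lower bound in size, at a dimmer one that averaged 3.35 in knockout-labelled samples, and Lyz1 gave -0.01. The mean shift of the list per sample was 0.28 and 0.82 in wild-type normoxia, 0.29 and 0.80 in wild-type hypoxia, -0.11 and -1.03 in knockout-labelled normoxia, and -0.08 and -0.98 in knockout-labelled hypoxia. Smooth muscle and pericyte markers also lay lower in knockout-labelled samples, at 0.43 and 0.10 in wild-type normoxia, 0.32 and 0.26 in wild-type hypoxia, -0.64 and -0.19 in knockout-labelled normoxia, and -0.13 and -0.15 in knockout-labelled hypoxia. That list had a median of -0.45, with 8 of 11 members lower, and did not pass (adjusted p = 0.0696). The calls over the list alone were 0 without wild-type normoxia replicate 2 or wild-type hypoxia replicate 2, and 1 without replicate 2 of either knockout-labelled group.

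The interferon-stimulated genes were lower in knockout-labelled samples in the same comparison, 26 of 28 members with a median of -0.71 (adjusted p = 7.8e-06; adjusted p = 0.859 with an estimated correlation). The median was -0.93 in normoxia (adjusted p = 5.85e-07; adjusted p = 0.824 with an estimated correlation) and -0.42 in hypoxia (adjusted p = 0.0231; adjusted p = 0.966 with an estimated correlation). No member was called over the list alone or over all genes with limma. The nucleic acid sensor Zbp1 had -1.55 (SE 0.30) and Gbp2 -0.68 (SE 0.18). In replicate 2 the mean shift of the list was 1.15 and 0.36 in wild-type normoxia and hypoxia. It was -0.59 and -1.03 in the knockout-labelled groups. In replicate 1 the genotypes overlapped, at -0.17 and 0.06 in wild-type cells and -0.27 and 0.49 in knockout-labelled cells. The call in normoxia was lost without wild-type normoxia replicate 2 (0.172). The call in hypoxia was lost without wild-type hypoxia replicate 1 (0.0673) or 2 (0.114), and turned in direction without knockout-labelled hypoxia replicate 2 (0.353). HIF targets were lower in knockout-labelled hypoxia, 30 of 35 with a median of -0.41 (adjusted p = 0.000252; adjusted p = 0.824 with an estimated correlation), and so were glycolysis genes, 25 of 26 with a median of -0.29 (adjusted p = 0.000501; adjusted p = 0.824 with an estimated correlation). These differences lay mostly in replicate 2. There the mean shift of the HIF list in hypoxia was 1.15 in wild-type and 0.20 in knockout-labelled cells, and that of glycolysis 0.73 and 0.009. In replicate 1 the HIF list lay at 0.51 and 0.58, the other direction, and glycolysis at 0.38 and 0.32. In normoxia neither list passed, at adjusted p of 0.224 and 0.0893. Both calls in hypoxia were lost without knockout-labelled hypoxia replicate 2 (0.0805 each) or wild-type hypoxia replicate 2 (0.403 for HIF targets and 0.133 for glycolysis).

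Averaged over oxygen, the HIF targets had a median of -0.19 between the genotypes (29 of 35 lower, adjusted p = 0.00336; adjusted p = 0.859 with an estimated correlation) and the glycolysis genes -0.18 (23 of 26 lower, adjusted p = 0.00186; adjusted p = 0.824 with an estimated correlation). Adjusted over the list alone 0 HIF targets and 3 glycolysis genes were called, Slc16a3 (-1.18, SE 0.25), Pfkfb4 (-0.95, SE 0.21) and Gys1 (-0.93, SE 0.20), and none over all genes with limma. The HIF call was lost without wild-type hypoxia replicate 2 (0.198), knockout-labelled normoxia replicate 1 (0.0858) or knockout-labelled hypoxia replicate 2 (0.0519), and the glycolysis call without wild-type hypoxia replicate 2 (0.0503). The 3 glycolysis genes became 0 without either replicate 2 hypoxia sample or either wild-type normoxia sample, 1 without wild-type hypoxia replicate 1 or knockout-labelled normoxia replicate 2, and 5 without knockout-labelled hypoxia replicate 1.

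**Figure D4:**
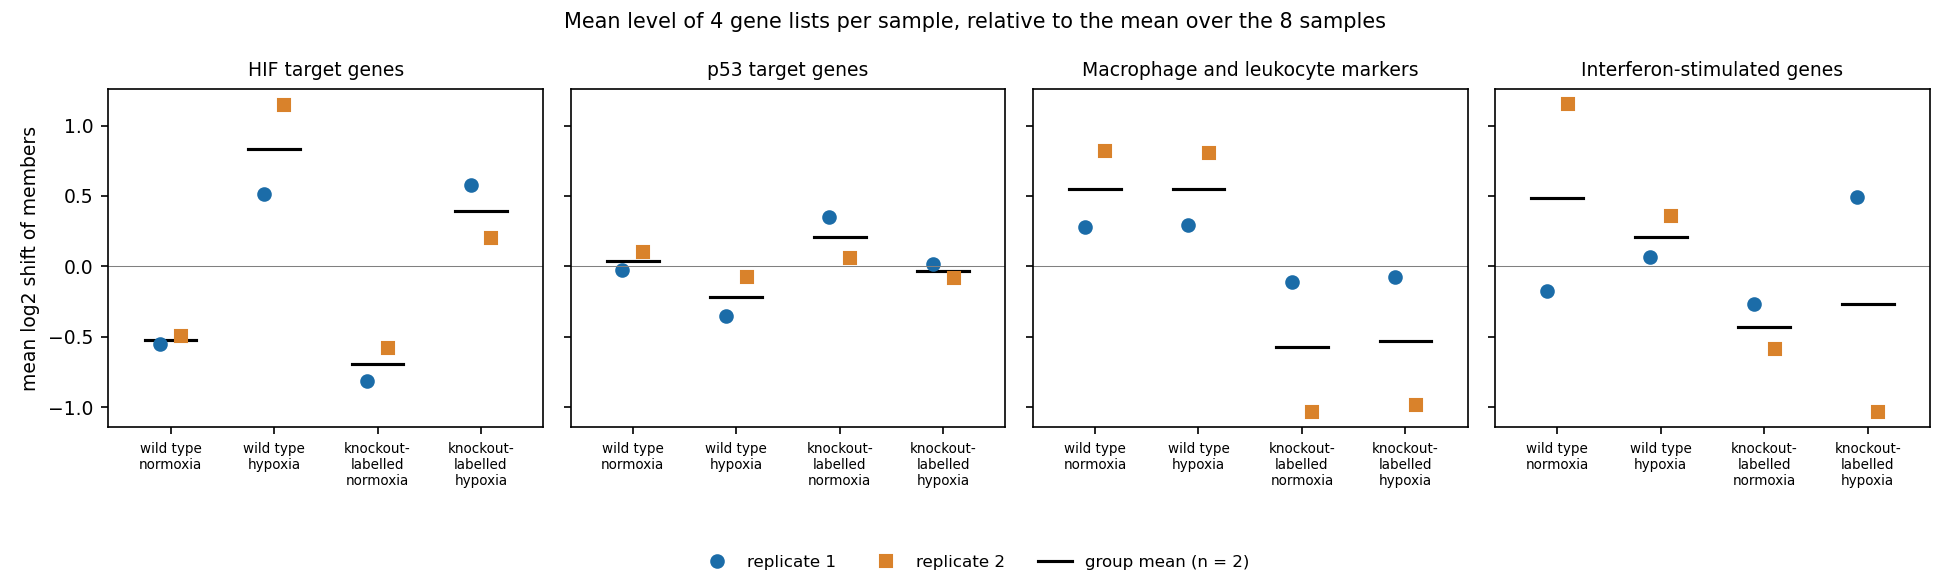
Mean log2 shift of the members of 4 gene lists in each sample, relative to the mean over the 8 samples, with circles for replicate 1, squares for replicate 2 and bars for the mean of the 2 samples of a group. The macrophage and leukocyte list lies at 0.82 and 0.80 in the wild-type replicate 2 samples and at -1.03 and -0.98 in the knockout-labelled ones.

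The remaining lists passed in none of the 7 comparisons. Their smallest adjusted p was 0.0646 for matrix and myofibroblast genes and for YAP and TEAD targets, 0.0636 for NF-kB targets, 0.0731 for collagen-modifying enzymes, 0.123 for cell cycle, sterol synthesis and immediate early genes, 0.174 for the unfolded protein and ATF4 response, 0.224 for NRF2 targets and for the oxygen-sensing list, 0.340 for Wnt targets and 0.693 for the respiratory chain. Among the markers it was 0.0696 for smooth muscle and pericytes, 0.168 for epicardium and mesothelium, 0.246 for sex-linked transcripts, 0.445 for adipocytes, 0.522 for cardiomyocytes, 0.654 for endothelium and for Schwann and neural cells, and 0.771 for fibroblasts and for skeletal muscle. The sex-linked list joins Xist, higher in knockout-labelled samples, with Y genes that were lower. A test for a common direction therefore does not measure whether its members differed. Adipocyte markers had a positive median beside a negative mean between the genotypes. Members called over their list alone between the genotypes, chosen after their values were seen, included the smooth muscle myosin Myh11 (-1.42, SE 0.25), desmin Des (-2.12, SE 0.41), the cytokine Tnf (-1.89, SE 0.37), elastin Eln (1.54, SE 0.23), the p53 target Perp (1.56, SE 0.30) and the mesothelial marker Upk3b (1.28, SE 0.14).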

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

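The tests of a culture difference, of the sex of the animals behind the macrophage markers, of a mislabelled sample, of a larger HIF response, of a related Siah gene and of oxygen labels exchanged within cultures were chosen after the result was seen; the other tests of explanations, and the splits of the samples, were set before. Wherever a bound was read against a standard error, the spread between samples was used, a choice made after the levels of the HIF and first macrophage lists had been seen.

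The interferon-stimulated genes stood out because their response to hypoxia differed between the genotypes in a test of the difference itself (adjusted p = 0.0201, median 0.39, 28 of 28 members higher). That call was lost at an adjusted p = 0.966 with an estimated correlation, and fry gave an adjusted p of 0.979. Per sample, the mean shift of that list was -0.17 and 1.15 in wild-type normoxia, 0.06 and 0.36 in wild-type hypoxia, -0.27 and -0.59 in knockout-labelled normoxia, and 0.49 and -1.03 in knockout-labelled hypoxia, and the direction turned without wild-type normoxia replicate 2 (adjusted p = 0.714) or knockout-labelled hypoxia replicate 1 (0.333).

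A signal also appeared among the 19035 spots that carry no gene name here and entered no comparison of genes, of which 11311 were bright enough to be tested. Spot 4896 averaged 2.58 (SD 0.09, n = 4) in wild-type samples and 8.91 (SD 0.18, n = 4) in knockout-labelled samples, a log2 fold change of 6.33 (SE 0.15, limma adjusted p = 7.39e-05). Spots 19648 (-3.82, SE 0.15) and 40100 (-2.54, SE 0.18) were lower in knockout-labelled samples. The lower genotype mean of each, 2.58, 2.79 and 3.23 in turn, lay under 3.39, the level below which named genes were left out as dim, and that of spot 4896 was at the 5th percentile of the arrays. These 3 differences are therefore bounded by background and give no fold beyond a lower bound. Of the spots tested limma called 3 between the genotypes, and none with hypoxia or for the difference of the responses.

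The lower macrophage and leukocyte markers in knockout-labelled samples were weighed against 3 explanations. A second list of macrophage genes, which shares no member with the other lists, was lower for 40 of 40 tested members with a median of -1.20 (SE of the list mean between samples 0.358; 35 called when adjusted over the list alone), which is consistent with a smaller share of macrophages in these cultures; the abundant Csf1r had means of 13.94 and 12.30, and smooth muscle and pericyte markers, which did not pass, were also lower (median -0.45, adjusted p = 0.0696), so a wider change in the cells stays open. A culture-to-culture difference unrelated to genotype stays open. Cultures were taken as genotype and replicate number, which the labels do not state. Their means of the first list were 0.287 and 0.813 for wild type and -0.0926 and -1.01 for knockout-labelled cells. An exact two-sided permutation test gave p = 0.333, the smallest that 6 arrangements allow. The sex of the animals stays open: 0 knockout-labelled samples had the Eif2s3y level of the wild type, and if that level marks sex, which was not settled, sex and genotype cannot be told apart. How far genotype itself may set the share of macrophages was not separable from these.

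Eif2s3y and Xist separated the genotypes in all 8 samples. A mislabelled sample stays open: that 0 samples lay nearer to the Eif2s3y mean of the other genotype restates the separation and decides nothing. Animals of different sex may account for it but stay open: genes known to escape X inactivation had a median log2 fold change of 0.38 (mean 0.29, SE between samples 0.0897), and 77.8% of the 9 were higher, under the 80% set beforehand. Eif2s3x went the other way, at -1.03. No biological explanation through Siah was tested.

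Siah2 reached the wild-type level in knockout-labelled hypoxia. Signal of a related Siah gene on the Siah2 spot is argued against, as the larger of the Siah1a and Siah1b changes with hypoxia in knockout-labelled cells was -0.21. A larger response of HIF targets in the knockout stays open: their median difference was -0.26 and their mean -0.27, with an SE between samples of 0.390. An altered Siah2 locus with a flanking segment from another strain also stays open, since 17.5% of the 40 nearest tested neighbours had an unadjusted p under 0.05 between the genotypes, at and not above the 95th percentile of 998 random windows (17.5, median 10). The windows of Siah1a, Siah1b and Siah3 gave 5, 15 and 2.5%.

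All 35 splits of the 8 samples into 4 and 4 were fitted in the same 2-group way. For hypoxia 3 splits gave at least as many called genes, with 8 genes for the real split, 165 for the split by genotype, which is a group of the design, and 1350 for the highest other. Chance is not excluded for that count. For genotype 2 splits did, with 165 genes for the real split and the same 1350 for the highest other, and chance is not excluded there either. The split with 1350 genes set knockout-labelled replicate 1 and wild-type replicate 2 against the rest, which points to a structure of the samples that the groups do not carry. For the shift of the HIF list with hypoxia 1 split was as large, the real one, at 1.22 against 0.875 for the highest other (adjusted p = 0.316 with an estimated correlation for the list). For the macrophage list between the genotypes 1 split was as large, the real one, at -1.10 against 0.922 in size. That list had a camera adjusted p = 0.960 with an estimated correlation. These splits exclude chance for either list only with the samples taken as exchangeable, which samples of a shared culture are not. For the next 2 tests the 4 cultures were assumed to be the pairs of genotype and replicate number, which the labels do not state. With the oxygen labels exchanged only within the 4 cultures, an exact two-sided permutation test of the HIF list gave p = 0.125, the smallest that 16 arrangements allow. For the macrophage list over the 4 cultures the exact p was 0.333, the smallest possible there.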

How the results depend on the processing

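The additive model, the crossed and culture blocks and the removal of X and Y genes were tests chosen after the results were seen; the other alternatives were set beforehand. An offset was not run, because the values were on the log2 scale. Of the values answering a comparison, 667 stayed the same. These were list p-values that kept direction and side of the threshold, and counts that stayed within 1.5 times, 0 against 0 included. Of the others, 61 counts moved by more than 1.5 times, 59 values lost a call, 6 gained a call and 4 reversed. Of 2809 values for 123 single-gene results, 2617 kept direction and side of the threshold, 71 lost a call, 115 gained one and 6 reversed, in 4 results. Apart from the estimated correlation and fry, no alternative or left-out sample ended the calls of HIF targets and glycolysis genes with hypoxia (highest adjusted p 1.28e-15 and 1.6e-06, in knockout-labelled cells), of macrophage markers between the genotypes (0.00254, in hypoxia), of interferon-stimulated genes in the average over oxygen (0.0177) or of p53 targets with hypoxia averaged over genotypes (0.0144). For the interferon-stimulated genes the genotypes lay apart in the replicate 2 samples and overlapped in replicate 1. Leaving out 1 sample at a time cannot show this. Where no cause is named, the cause was not tested. Signal over background limits the dim part of the array, with 49.4% of the named genes, each read at its brightest spot, below a mean of 5, and 220 genes above a mean of 15 lie near the top of the scale.

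With the replicate number as a block the count between the genotypes averaged over oxygen was 1, and the glycolysis calls over the list alone in that comparison were 0; this block changed no other list call or count. The numbers were not taken to pair samples. Deviations of same-numbered samples correlated across genes at 0.308 in wild-type and 0.338 in knockout-labelled cells across oxygen. Across genotypes they correlated between -0.378 and -0.262, about as strongly but with the sign turned. These values therefore do not tell cultures shared within a genotype from a grouping of knockout-labelled replicate 1 with wild-type replicate 2. With crossed numbers as a block the count between the genotypes averaged over oxygen was 453 and the glycolysis count 6. The HIF difference of responses then passed camera at an adjusted p of 0.0182. With the culture as a fixed block the HIF difference passed at 0.0387. With the culture as a random block (consensus correlation 0.431) the counts were 1 between the genotypes averaged over oxygen and 15 with hypoxia averaged over genotypes. 

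The additive model gave 103 genes between the genotypes averaged over oxygen (40 higher and 63 lower), 8 with hypoxia averaged over genotypes, and 5 glycolysis genes over the list alone between the genotypes. A variance trend gave 62 (19 higher and 43 lower), 15, and 14 glycolysis genes over the list alone in wild-type cells. Removing the dimmest 50% of genes gave 45 (14 higher and 31 lower) between the genotypes, 3 in normoxia, and a HIF difference at 0.0155; no filter gave 5 glycolysis genes over the list alone between the genotypes. Every spot as a feature gave 21 between the genotypes, 4 in hypoxia and 3 in normoxia. Without X and Y genes, which removes Eif2s3y by construction, and with only the compared groups fitted, which leaves fewer samples, 0 genes were called in limma in normoxia and 0 in hypoxia. The mean over spots gave 8 HIF calls over the list alone with hypoxia in knockout-labelled cells, 0 glycolysis calls between the genotypes and 0.0581 for p53 targets in wild-type cells.

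With an estimated correlation every list call was lost: adjusted p was 0.316 for HIF targets and glycolysis genes with hypoxia in wild-type cells, knockout-labelled cells and the average; 0.824 for glycolysis between the genotypes in hypoxia and the average, and for HIF targets in hypoxia, with 0.859 in the average; 0.824, 0.966 and 0.859 for interferon-stimulated genes in normoxia, hypoxia and the average, and 0.966 for their difference; 0.960 for macrophage markers in all 3; and 0.824, 0.824 and 0.796 for p53 targets in wild-type cells, knockout-labelled cells and the average. With fry, which tests the list itself and not against other genes, the values were 0.145, 0.177 and 0.145 for HIF targets and again 0.145, 0.177 and 0.145 for glycolysis with hypoxia in wild-type cells, knockout-labelled cells and the average. Between the genotypes fry gave 0.508 and 0.508 for glycolysis and 0.705 and 0.711 for HIF targets in hypoxia and the average, 0.711, 0.969 and 0.705 for interferon-stimulated genes and 0.470, 0.470 and 0.433 for macrophage markers in normoxia, hypoxia and the average. It gave 0.979 for the interferon difference, and 0.566, 0.578 and 0.439 for p53 targets.

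Leaving out each sample in turn, a lone sample being assumed to vary like the other groups, gave these lowest and highest values. The adjusted p ranged from 6.1e-06 to 0.761 for the HIF difference and from 7.2e-10 to 0.714 for the interferon difference, from 0.000133 to 0.0503 for glycolysis between the genotypes and from 2.69e-05 to 0.133 in hypoxia, from 6.1e-06 to 0.198 for HIF targets between the genotypes and from 3.22e-08 to 0.403 in hypoxia. It ranged from 1.23e-11 to 0.172 for interferon-stimulated genes in normoxia and from 4.29e-09 to 0.353 in hypoxia, and for p53 targets from 0.000956 to 0.263 in wild-type and from 0.000220 to 0.400 in knockout-labelled cells. The genes called ranged from 1 to 12 between the genotypes averaged over oxygen, 0 to 8 in hypoxia, 0 to 1 in normoxia, 0 to 4 with hypoxia averaged over genotypes, 0 to 7 in knockout-labelled cells, 0 to 1 in wild-type cells and 0 to 7 for the difference. Calls over the list alone ranged from 7 to 24 for HIF targets in wild-type and 0 to 13 in knockout-labelled cells, from 0 to 8 and 2 to 6 for glycolysis, and between the genotypes from 0 to 5 for glycolysis and 0 to 14 for macrophage markers. The values that reversed were the interferon difference without knockout-labelled hypoxia replicate 1 (0.333) or wild-type normoxia replicate 2 (0.714), the HIF difference without wild-type hypoxia replicate 2 (0.761) and interferon-stimulated genes in hypoxia without knockout-labelled hypoxia replicate 2 (0.353). Among uncalled genes Siah1a reversed for the difference (-0.20 to 0.077), Siah2 between the genotypes in hypoxia (-0.47 to 0.12, with 0.03 without knockout-labelled hypoxia replicate 2), and Siah3 in knockout-labelled cells (-0.44 to 0.18) and in hypoxia (-1.42 to 0.88, with 0.04 without knockout-labelled hypoxia replicate 1).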

Other observations

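The genes here were chosen after their values were seen, and the tests with an additive model or culture block were chosen after the results were seen. Averaged over the genotypes, the placental growth factor Pgf (log2 fold change 3.71, SE 0.33 under the additive model, 4 samples against 4) and the vasoactive peptide Apln (3.56, SE 0.35) were among the genes that passed with hypoxia under both the additive model and the variance trend, though not in the 4-mean fit of limma (adjusted p = 0.147 for each). Beside them stood the inositol kinase Itpk1 (2.49), Prr15 (2.57), Prelid2 (2.07), the kinase Sik1 (2.05), Bnip3 (2.55) and Pfkl (1.33).

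Between the genotypes, the BMP antagonist Grem1 was lower in knockout-labelled cells (-3.68, SE 0.35) under the additive model, as were the homeobox genes Hoxc6 (-2.75) and Hoxc4 (-1.96), whose knockout-labelled means of 3.15 and 3.30 lay under the dim level of 3.39, so that their differences are lower bounds in size. The Fc receptor Fcgr2b (-2.30) and the chemokine Ccl4 (-1.47), both known from leukocytes, the microfibril gene Mfap2 (-2.28) and the water channel Aqp1 (1.29, higher) passed in the same way, and Wdfy1 was higher (2.93). None of these genes was called in the 4-mean fit, nor with the culture as a random block, where Eif2s3y was the 1 gene called between the genotypes.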
